A study of Mus musculus with 13 samples.

How the data were processed

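RNA was isolated from sciatic nerve of BKS db/+ and db/db mice at 24 weeks, amplified, labelled with biotin and hybridised to 1-colour Affymetrix arrays, per the labels' protocols. The deposited values are log2 expression levels made by the authors with RMA, per the submitters' processing notes, and were used as deposited. RMA corrects background, normalizes arrays to each other and summarises probes, so that differences in total signal between arrays are removed and folds of dim genes are compressed. The RMA version, the array platform and the probe set definition are not given in the sources used here. The values carry no detection calls, so levels near the bottom of the range (1.75 to 16.37 over all arrays) were not separated from background.

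The table held 15479 probe sets, of which 42 were Affymetrix controls and stayed out of the tests, leaving 15437. A table of probe sets and gene symbols paired 14801 of these with 1 symbol, 636 with none and 0 with several, and 14776 of the symbols were found in a RefSeq gene table, which changed 0 of them. A listed symbol was matched through a synonym only where it was not itself the symbol of another gene. Each gene had 1 probe set, so counting probe sets in place of genes gave nothing further. Coordinates are not printed because no build is named for the probe sets. The RefSeq table served to match symbols and to find the neighbours of Lepr.

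Samples were grouped by the genotype in their labels, giving 7 db/+ and 6 db/db arrays. The sample numbers run from 101 to 112 and from 404 to 411, and what the numbers mark is not stated. They were treated as 2 number series, with 5 db/+ and 3 db/db arrays in the lower series and 2 db/+ and 3 db/db arrays in the higher one. Genotype was tested for every gene with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over the 15437 genes and a threshold of 0.05. Standard errors come from the same fit. Gene lists were tested with limma's camera at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over 29 lists. The lists had 561 entries, of which 481 were measured. They covered myelin and repair Schwann cells, cholesterol synthesis, fatty acid synthesis, adipocytes, fatty acid oxidation, skeletal muscle, macrophages, lymphocytes, mast cells, neutrophils, extracellular matrix, perineurial, endothelial, pericyte, neuronal and erythroid genes, oxidative phosphorylation, glycolysis, antioxidants, endoplasmic reticulum stress, the circadian clock, interferon, cytokines, the cell cycle, apoptosis, immediate early genes, insulin and leptin signalling, and ion channels. Members were counted over all genes tested and also with the adjustment over the list alone. Lists, tests and the rule for named genes were set before the data were examined.

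The rule named Lepr, the 10 greatest rises and the 10 greatest falls among genes past the threshold, the 3 members with the smallest p of each list that passed camera or had 3 or more members past the gene threshold, and the 1 member with the smallest p of every other list. It gave 92 genes. Genes outside the rule are said to have been chosen after their values were seen.

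The fit was tested on simulated data for the 15437 genes with 200 changed between groups of the same sizes. It recovered 74% of the genes changed by 1 and 98% of those changed by 2 on the log2 scale, with 12 false calls among 184. Camera called the 1 list shifted by 0.7 and 0 of the other 28. The simulated genes varied independently of each other. In the 7 real lists that passed camera, the estimated correlation between genes ran from 0.119 (repair Schwann cell) to 0.897 (neuronal). The 0 false list calls therefore do not test camera at its preset correlation in lists of correlated genes. Other settings fixed beforehand were moderation with an intensity trend, with or without robust moderation, renewed quantile normalization, median centring, filters on dim genes, array weights, the number series as a block or each series alone, leaving out each array, thresholds on size, an exact rank-sum test, fry, an estimated correlation, and list means as covariates. Leaving out db/+ 101, 103, 104 and 106, with or without the series as a block, and the neuronal list mean as a covariate were added after the data were seen, as were the camera test of the difference between the number series, the estimated correlation within sets of arrays and the tracing of genes called in arrays 101 to 112 through arrays 404 to 411. Other calculations used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.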

Results

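Gene expression was measured in the sciatic nerve of BKS mice at 24 weeks of age. The db mutation disrupts the leptin receptor gene Lepr, and homozygous db/db mice become obese and diabetic, whereas heterozygous db/+ mice serve as the nondiabetic control. The comparison asked which transcripts differ between db/db and db/+ nerve in this model of the neuropathy of type 2 diabetes. The set held 13 arrays, 7 of db/+ nerve (samples 101, 103, 104, 105, 106, 404 and 407) and 6 of db/db nerve (samples 110, 111, 112, 409, 410 and 411). The values were log2 expression levels for 15437 genes. Array medians lay between 8.63 and 8.71, and correlations between pairs of arrays across genes ranged from 0.895 to 0.989, with 0 identical pairs. The labels number each sample as a mouse sample but do not state that each came from a separate animal. The p-values therefore measure the spread between these samples, and the number of arrays limits the precision.

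Sciatic nerve of db/db mice differed from that of db/+ mice in a large part of the measured transcripts. Cell cycle, adipocyte and fatty acid oxidation genes were higher in db/db nerve, and myelin, Schwann cell, ion channel and neuronal genes were lower. These 7 lists passed camera at its preset correlation, 0 passed with an estimated correlation (adjusted p = 0.778 for each), and the repair Schwann cell, ion channel and neuronal lists did not pass in arrays 404 to 411. The genes with the greatest rises were Tph2, which encodes the neuronal enzyme of serotonin synthesis, at 12.29 ± 0.21 (SD, n = 6) in db/db against 6.04 ± 0.73 (SD, n = 7) in db/+, and Lipf, which encodes gastric lipase, at 9.87 ± 0.31 against 3.95 ± 0.32. Neuronal transcripts fell the most, and this difference came with a division among the db/+ arrays. The mean of the neuronal list was 12.49, 12.25, 11.77 and 11.98 in db/+ 101, 103, 104 and 106, but 8.59, 8.02 and 7.62 in db/+ 105, 404 and 407, and it lay between 6.91 and 7.80 in the 6 db/db arrays. Adjusted p-values are Benjamini-Hochberg adjusted throughout, from limma for genes and from camera for gene lists. By limma with Benjamini-Hochberg adjustment, 3867 of the 15437 genes passed an adjusted p of 0.05, 2068 of them higher and 1799 lower in db/db. Counts of list members past this threshold are to be read against that share. The groups did not overlap in 1495 genes (9.68%, where chance gives 0.117%).

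The same count was 1992 genes (945 higher, 1047 lower) when db/+ 101, 103, 104 and 106 were left out, a choice made after the values were seen, and 802 of the higher and 634 of the lower genes kept their call. Of 91 genes named here besides Lepr, 37 lost their call without those 4 arrays, and in arrays 404 to 411, which are fewer, 51 did besides Nap1l2. Arrays numbered 404 to 411 alone, 2 of db/+ and 3 of db/db, gave 1404 genes (761 higher, 643 lower), arrays 101 to 112 gave 2858, and a fit with the number series as a block gave 4227. The mean of the adipocyte list was higher on every db/db array than on every db/+ array, and with it as a covariate 541 genes passed (236 higher, 305 lower). With that covariate the cell cycle and cholesterol lists passed camera, and the neuronal, ion channel, myelin, repair Schwann cell and fatty acid oxidation lists did not. As that mean separates the genotypes, this fit cannot divide a change between genotype and adipocyte transcripts. The difference between the genotype effects of the 2 number series passed the adjusted threshold for 0 genes by limma, and 2360 genes had an unadjusted p below 0.05. With an estimated correlation camera passed 0 lists without the 4 arrays, in either number series and with the series as a block.

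**Figure D1:**
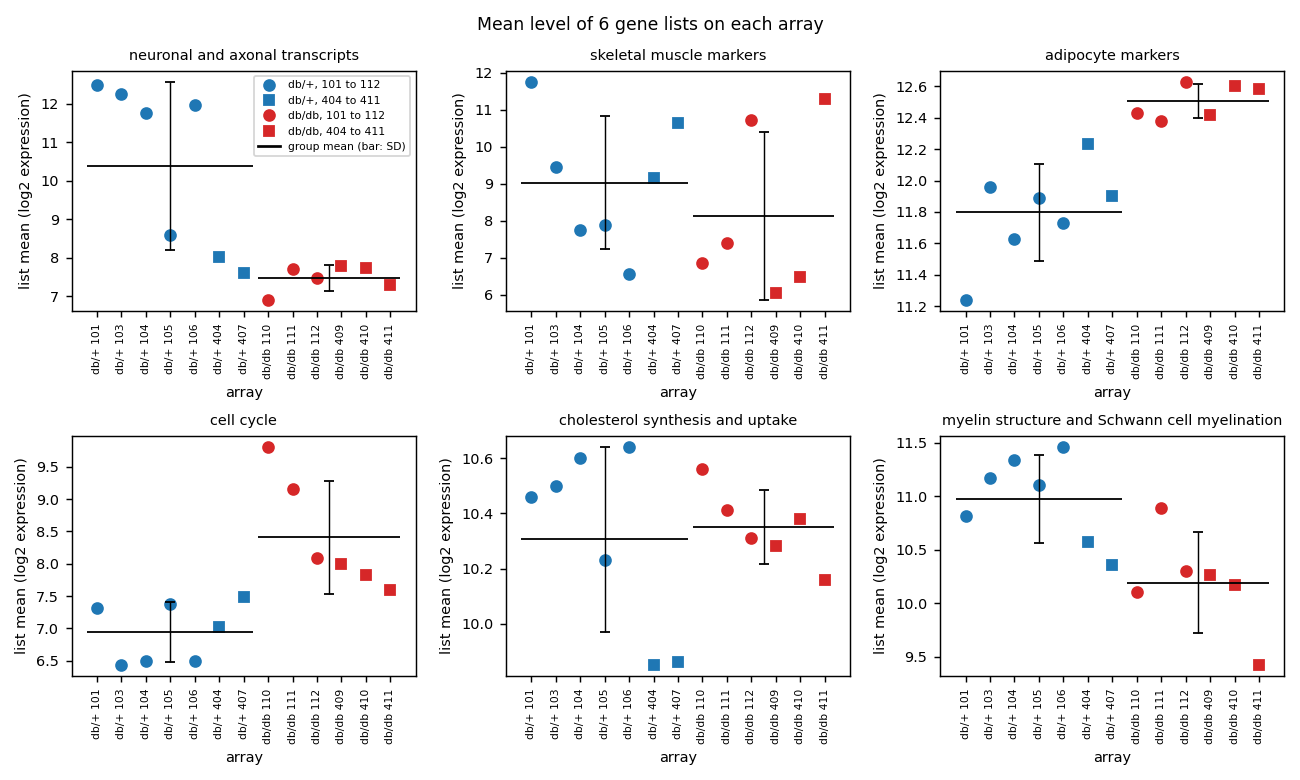
Mean log2 expression of the members of 6 gene lists (vertical axes) on each of the 13 arrays (horizontal axes), with circles for samples 101 to 112, squares for samples 404 to 411, and lines and bars for the group means and SDs. The neuronal list lies between 11.77 and 12.49 in db/+ 101, 103, 104 and 106 and at or below 8.59 on the other 9 arrays, while the adipocyte list is higher on each db/db array than on each db/+ array.

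Lepr itself was lower in db/db nerve on every array. Its level was 6.78, 7.20, 7.24, 8.04, 7.34, 8.98 and 8.45 in db/+ 101, 103, 104, 105, 106, 404 and 407, and 5.85, 6.20, 6.50, 6.56, 6.14 and 6.54 in db/db 110, 111, 112, 409, 410 and 411. The means were 7.72 ± 0.79 (SD, n = 7) and 6.30 ± 0.28 (SD, n = 6). Lepr fell by 1.42 on the log2 scale with an SE of 0.32 (limma, Benjamini-Hochberg adjusted p = 0.00659). With the number series as a block it fell by 1.59, and in arrays 404 to 411 it fell by 2.30 (limma, Benjamini-Hochberg adjusted p = 0.0132). The mutation alters splicing of the long receptor form, so a probe set outside the altered part need not have moved.

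The 10 genes with the greatest rises belonged to several kinds of tissue function. Tph2 rose by 6.25 ± 0.29 (SE) on the log2 scale and Lipf by 5.92 ± 0.17, with limma's Benjamini-Hochberg adjusted p of 2.88e-08 and 3.08e-10. Prr32 rose by 5.17, the oxytocin receptor gene Oxtr by 5.05, and Ucp1, the uncoupling protein of brown fat, by 4.80. The immunoglobulin heavy chain genes Ighg1 and Ighg2b rose by 4.62 and 4.08, although probe sets for such closely related genes can share signal. Chil3, a chitinase-like protein of activated macrophages, rose by 4.51, the ubiquitin-like modifier gene Ubd by 4.32, and Olr1, a receptor for oxidized low-density lipoprotein, by 4.14. For 8 of these 10 the rise passed the threshold without db/+ 101, 103, 104 and 106 and also in arrays 404 to 411, which are 5 of the 9 arrays left. Chil3 and Ighg2b did not. They stood at 3.90 and 3.18 without the 4 arrays (limma, Benjamini-Hochberg adjusted p = 0.0744 and 0.169) and at 2.98 and 2.08 in arrays 404 to 411 (adjusted p = 0.288 and 0.383).

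The gene with the greatest fall was Cadps, which primes secretory vesicles and fell by 4.81 ± 0.88 (SE) on the log2 scale. The neuronal tubulin gene Tubb3 fell by 4.78, and the glutamate receptor gene Grm7 fell by 4.46. The neural transcription factor gene Myt1 fell by 4.35, Nap1l2 fell by 4.23, the nociceptor sodium channel gene Scn11a fell by 4.22, and Snap91 fell by 4.15. The vesicular glutamate transporter gene Slc17a6 fell by 4.05 and AI593442 fell by 4.04. Without db/+ 101, 103, 104 and 106, the arrays with high neuronal transcripts, 4 of the 10 greatest falls (Cadps, Tubb3, Grm7 and Cyp2f2) passed the threshold, and in arrays 404 to 411 Cadps, Grm7 and Cyp2f2 did. Scn11a missed the threshold when any 1 of 10 arrays was left out and Slc17a6 for any 1 of 9, and Nap1l2 stood at 0.13 above db/+ in arrays 404 to 411 (limma, Benjamini-Hochberg adjusted p = 0.814). Cyp2f2, a cytochrome P450 gene, fell by 4.27 ± 0.46 (SE) over all arrays and fell by 5.16 without the 4 arrays (limma, Benjamini-Hochberg adjusted p = 5.17e-05 and 0.000528).

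**Figure D2:**
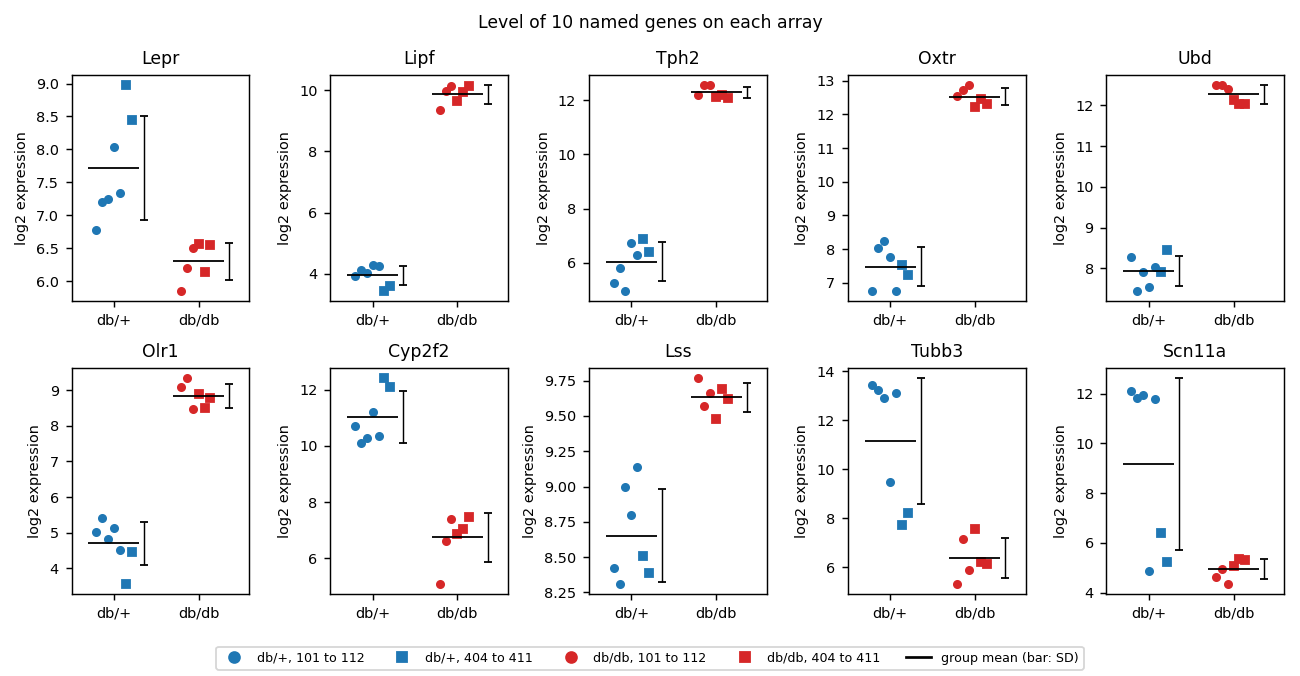
Log2 expression (vertical axes) of 10 genes on each array in db/+ (blue) and db/db (red), with circles for samples 101 to 112, squares for samples 404 to 411, and lines and bars for the group means and SDs. Lipf, Tph2, Oxtr, Ubd and Olr1 separate the genotypes on every array, whereas Scn11a is between 11.8 and 12.1 in db/+ 101, 103, 104 and 106 and at or below 6.38 on the other 9 arrays.

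Neuronal and axonal transcripts were lower in db/db nerve. Of 13 measured members 8 fell, 0 rose and 5 did not pass the test over all genes, and 12 fell when adjusted over the list alone. The median log2 fold change was −3.34 (camera, Benjamini-Hochberg adjusted p = 1.67e-05), with adjusted p = 0.778 with an estimated correlation. The ubiquitin hydrolase gene Uchl1 fell by 2.21 ± 0.33 (SE) on the log2 scale, the splicing factor gene Rbfox3 fell by 2.78 ± 0.63, and Tubb3 is given above. The median was −2.92 with the number series as a block, −4.49 in arrays 101 to 112 and −0.32 in arrays 404 to 411. The list did not pass in arrays 404 to 411 (camera, Benjamini-Hochberg adjusted p = 0.801) or without db/+ 101, 103, 104 and 106 (median −0.76, adjusted p = 0.221). Single members still passed without those 4 arrays, 4 lower and 1 higher, and Uchl1 fell by 1.40 and Rbfox3 by 1.12 there (limma, Benjamini-Hochberg adjusted p = 0.00576 and 0.0211). The 3' minus 5' difference of the actin control probe sets, a measure of RNA quality, was 0.96 to 1.39 in those 4 arrays, 0.40 to 1.14 in db/+ 105, 404 and 407, and 0.48 to 0.92 in db/db.

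Genes of ion channels and nodes of Ranvier were also lower. Of 17 members 9 fell and 8 did not pass, and 10 fell and 1 rose when adjusted over the list alone. Its median log2 fold change was −1.02 (camera, Benjamini-Hochberg adjusted p = 0.00425), with adjusted p = 0.778 with an estimated correlation. Kcnmb4, a subunit of calcium-activated potassium channels, fell by 1.08, the inward rectifier gene Kcnj10 fell by 2.60, and Cntnap2, which encodes a protein beside the node, fell by 3.34. The list mean was between 9.26 and 9.29 in db/+ 101, 103, 104 and 106, the arrays with high neuronal transcripts, and between 7.25 and 7.70 on the other 9. Its median was −0.87 with the number series as a block (camera, Benjamini-Hochberg adjusted p = 0.014) and −1.18 in arrays 101 to 112 (adjusted p = 0.00057). It did not pass in arrays 404 to 411 (median −0.26, adjusted p = 0.591) or without the 4 arrays (median −0.29, adjusted p = 0.619). Without them Kcnmb4, Kcnj10 and Cntnap2 stood at −0.70, −0.64 and −0.79 and lost their calls (limma, Benjamini-Hochberg adjusted p = 0.158, 0.0759 and 0.131), although Kcnj10 passed in arrays 404 to 411 (−0.81, adjusted p = 0.0282).

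Myelin genes were lower in db/db nerve. Of 17 members 10 fell and 7 did not pass, and 15 fell when adjusted over the list alone. The median log2 fold change was −0.77 (camera, Benjamini-Hochberg adjusted p = 9.51e-06), with adjusted p = 0.778 with an estimated correlation. Cldn19, a tight junction gene of myelin, fell by 1.43 ± 0.30 (SE) on the log2 scale, the connexin gene Gjb1 fell by 1.29 ± 0.28, and Drp2, which organises the outer Schwann cell membrane, fell by 1.21 ± 0.29. The list mean was between 10.36 and 11.46 in db/+ and between 9.42 and 10.89 in db/db. The median was −0.65 with the number series as a block (camera, Benjamini-Hochberg adjusted p = 2.6e-05), −0.73 in arrays 101 to 112 (adjusted p = 3.48e-06) and −0.57 in arrays 404 to 411 (adjusted p = 0.0324). Without db/+ 101, 103, 104 and 106 it was −0.51 and missed the threshold (adjusted p = 0.0644), and 0 members passed over all genes (limma), but with the number series as a block on those 9 arrays it was −0.61 and passed (adjusted p = 0.00711). The list did not pass with the adipocyte list mean as a covariate (median −0.44, camera with Benjamini-Hochberg adjusted p = 0.341) or with the neuronal list mean (median −0.37, adjusted p = 0.215).

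Genes of repair or immature Schwann cells went mostly down. Of 14 members 7 fell, 1 rose and 6 did not pass, and 8 fell and 2 rose when adjusted over the list alone. The median log2 fold change was −0.69 (camera, Benjamini-Hochberg adjusted p = 0.0264), with adjusted p = 0.778 with an estimated correlation. The neurotrophin receptor gene Ngfr fell by 1.21 and the adhesion molecule gene Ncam1 fell by 1.14, while Btc, which encodes betacellulin, rose by 1.46 ± 0.28 (SE) on the log2 scale. The list mean was between 8.17 and 8.45 in db/+ 101, 103, 104 and 106, where neuronal transcripts were high, and between 6.83 and 7.40 on the other 9 arrays. The median was −0.70 with the number series as a block (camera, Benjamini-Hochberg adjusted p = 0.0663), −1.07 in arrays 101 to 112 (adjusted p = 0.0157) and −0.50 in arrays 404 to 411 (adjusted p = 0.591). Without the 4 arrays it was −0.38 (adjusted p = 0.599) and Ncam1 lost its call (limma adjusted p = 0.199), while Btc and Ngfr kept theirs. The list also missed the threshold without db/+ 103 (adjusted p = 0.0558) or without db/db 110 (adjusted p = 0.0527).

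Cell cycle genes rose in db/db nerve. Of 19 members 16 rose and 3 did not pass, and all 19 rose when adjusted over the list alone. Their median log2 fold change was 1.47 (camera, Benjamini-Hochberg adjusted p = 1.19e-06), with adjusted p = 0.778 with an estimated correlation. The mitotic kinase gene Cdk1 rose by 2.33 ± 0.35 (SE), the cyclin gene Ccnb2 by 2.46 ± 0.50 and Birc5, which encodes survivin, by 2.25 ± 0.47. The list mean was 9.81 and 9.15 in db/db 110 and 111, between 7.60 and 8.09 in the other 4 db/db arrays, and between 6.43 and 7.48 in db/+. In db/+ 103, 104 and 106, which had high neuronal transcripts, it was 6.43 to 6.50, and in db/+ 101, which had them too, it was 7.32. The median was 1.56 with the number series as a block, 2.21 in arrays 101 to 112, 0.55 in arrays 404 to 411 and 1.12 without the 4 arrays, and camera's adjusted p at the preset correlation passed in each (Benjamini-Hochberg adjusted p = 1.18e-06, 7.12e-09, 0.00151 and 3.56e-05). In these last 2 sets 2 members and 1 member passed over all genes. Without the 4 arrays Ccnb2 and Birc5 stood at 2.18 and 1.92 and missed the threshold (limma adjusted p = 0.0708 and 0.0564).

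Adipocyte markers rose. Of 16 members 10 rose and 6 did not pass, and 12 rose when adjusted over the list alone. The median log2 fold change was 0.69 (camera, Benjamini-Hochberg adjusted p = 9.51e-06), with adjusted p = 0.778 with an estimated correlation. The leptin gene Lep rose by 1.75 ± 0.25 (SE) on the log2 scale, the glycerol channel gene Aqp7 by 1.62 ± 0.22 and the fatty acid transporter gene Cd36 by 0.87 ± 0.11. The list mean was between 12.38 and 12.63 in db/db and between 11.24 and 12.23 in db/+, where the lowest 3 values came from db/+ 101, 104 and 106, arrays with high neuronal transcripts. The median was 0.60 with the number series as a block, 0.73 in arrays 101 to 112, 0.37 in arrays 404 to 411 and 0.44 without the 4 arrays (camera, Benjamini-Hochberg adjusted p = 2.6e-05, 3.15e-05, 0.00206 and 2.87e-05). In these last 2 sets, which hold fewer arrays, 3 and 6 members passed over all genes.

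Genes of fatty acid oxidation and targets of the PPAR receptors rose as well. Of 20 members 12 rose and 8 did not pass, and 14 rose when adjusted over the list alone. Their median log2 fold change was 0.40 (camera, Benjamini-Hochberg adjusted p = 1.08e-05), with adjusted p = 0.778 with an estimated correlation. The lipid droplet gene Plin2 rose by 1.20 ± 0.12 (SE) on the log2 scale, Slc25a20, the carnitine carrier of mitochondria, by 0.64 ± 0.10 and Etfdh, which passes electrons from fatty acid oxidation to the respiratory chain, by 0.61 ± 0.09. The median was 0.39 with the number series as a block, 0.38 in arrays 101 to 112, 0.33 in arrays 404 to 411 and 0.34 without the 4 arrays (camera, Benjamini-Hochberg adjusted p = 2.6e-05, 0.000152, 0.00151 and 3.25e-05). In these last 2 sets, which hold fewer arrays, 3 and 7 members passed over all genes. The adipocyte list mean was higher on every db/db array too, and with that mean as a covariate the fatty acid oxidation list did not pass (median 0.10, camera with Benjamini-Hochberg adjusted p = 0.269). Because the covariate separates the genotypes, the lost call does not show that adipocyte content accounts for the rise.

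Among other lipid genes, the lists did not pass over all arrays. Of 16 measured genes of cholesterol synthesis and uptake 3 rose and 1 fell, with the same counts adjusted over the list alone, and the median was −0.01 (camera, Benjamini-Hochberg adjusted p = 0.863). The synthesis enzyme genes Lss, Nsdhl and Sc5d rose by 0.98 ± 0.14 (SE), 0.69 ± 0.13 and 0.48 ± 0.13 on the log2 scale. The list mean was between 10.16 and 10.56 in db/db, 9.85 and 9.86 in db/+ 404 and 407, 10.23 in db/+ 105, and between 10.46 and 10.64 in db/+ 101, 103, 104 and 106, where neuronal transcripts were high. Without those 4 arrays 6 members rose and the median was 0.31 (camera, Benjamini-Hochberg adjusted p = 0.00023), in arrays 404 to 411 it was 0.42 (adjusted p = 0.00151), and in arrays 101 to 112 it was −0.10 (adjusted p = 0.679). With an estimated correlation the adjusted p of camera for this list was 0.985 over all arrays, 0.788 without the 4 arrays and 0.865 in arrays 404 to 411, so those calls hold only at the preset correlation. Of 18 genes of fatty acid and triglyceride synthesis 2 rose and 1 fell, also when adjusted over the list alone (median −0.03, camera adjusted p = 0.939). The phosphatidate phosphatase gene Lpin1 rose by 0.65, the triglyceride synthesis gene Dgat2 rose by 1.06 and the elongase gene Elovl6 fell by 0.87. Elovl6 stood at −0.45 without the 4 arrays and lost its call (limma adjusted p = 0.27), while Lpin1 and Dgat2 kept theirs.

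**Figure D3:**
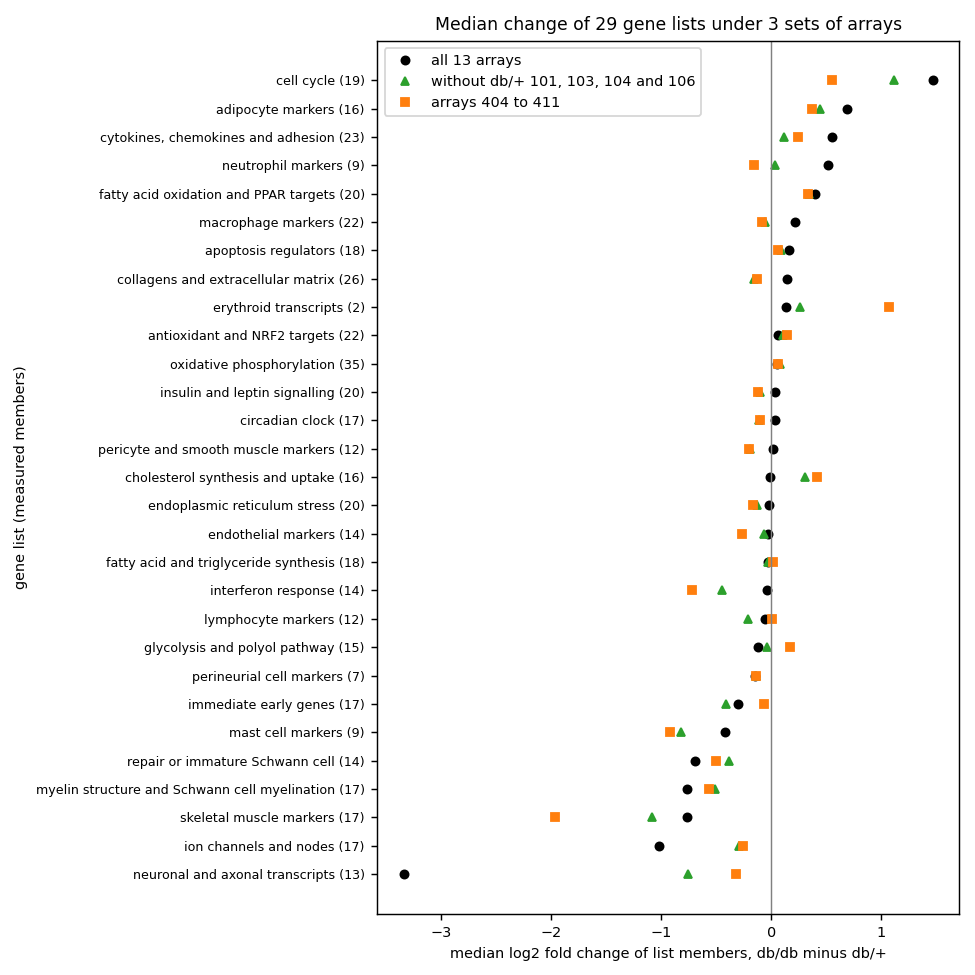
Median log2 fold change of the measured members (horizontal axis, db/db minus db/+) of 29 gene lists (vertical axis, members in parentheses) over all 13 arrays, without db/+ 101, 103, 104 and 106, and in arrays 404 to 411. The neuronal list moves from −3.34 to −0.76 and −0.32, and the fatty acid oxidation list stays between 0.33 and 0.40.

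Immune cell markers changed as individual genes. Of 22 macrophage markers 8 rose and 14 did not pass, and 8 rose and 1 fell when adjusted over the list alone (median 0.22, camera with Benjamini-Hochberg adjusted p = 0.074). Trem2, a lipid-sensing receptor, rose by 2.17 ± 0.35 (SE) on the log2 scale, Gpnmb by 1.61 ± 0.21 and Cd68 by 1.38 ± 0.33. Without db/+ 101, 103, 104 and 106 Cd68 stood at 0.90 and lost its call (limma adjusted p = 0.169), while Trem2 and Gpnmb kept theirs. Of the macrophage list 2 members passed there as higher and 2 as lower (median −0.06). The macrophage list mean was between 11.19 and 11.41 in db/+ 101, 103, 104 and 106, where neuronal transcripts were high, and between 11.47 and 12.13 on the other arrays. The list passed in arrays 101 to 112 (median 0.40, camera with Benjamini-Hochberg adjusted p = 0.00221) but not there with an estimated correlation (adjusted p = 0.923), and its median was −0.08 in arrays 404 to 411 (adjusted p = 0.853). Of 23 cytokine, chemokine and adhesion genes 7 rose and 1 fell, and 9 rose and 2 fell when adjusted over the list alone (median 0.55, adjusted p = 0.074). The monocyte attractant gene Ccl2 rose by 1.81 and Ccl4 rose by 1.5, while the interleukin gene Il18 fell by 1.27 ± 0.12 (SE). Without the 4 arrays 0 members of this list passed as higher and 3 as lower (median 0.12). Ccl2 and Ccl4 stood there at 1.47 and 1.15 and missed the threshold (limma adjusted p = 0.0547 and 0.0974). In arrays 404 to 411 they stood at 1.94 and 1.52 and missed it too (limma adjusted p = 0.0818 and 0.0624), and Il18 passed in both sets. Of 9 neutrophil markers 2 rose and 1 fell, also when adjusted over the list alone (median 0.52, adjusted p = 0.297), with S100a8 up by 2.72, Mmp8 up by 2.22 and Mmp9 down, at a log2 change of −1.33. Mmp8 stood at 1.58 without the 4 arrays and lost its call (limma adjusted p = 0.241), and S100a8 and Mmp9 kept theirs. Of 12 lymphocyte markers 1 rose, the cytokine receptor gene Il7r by 3.46 ± 0.34 (SE), also when adjusted over the list alone (median −0.06, adjusted p = 0.939). Of 9 mast cell markers 2 fell, also when adjusted over the list alone (median −0.42, adjusted p = 0.0797), among them the carboxypeptidase gene Cpa3, which fell by 0.66 and lost its call when any 1 of 7 arrays was left out. The mast cell list passed without db/+ 101, 103, 104 and 106 (median −0.82, adjusted p = 0.00321) and in arrays 404 to 411 (median −0.92, adjusted p = 0.0184), but only at the preset correlation. With an estimated correlation its adjusted p in camera was 0.985 over all arrays, 0.908 without the 4 arrays and 0.865 in arrays 404 to 411. Of 14 interferon response genes 1 rose, Cxcl10 by 1.89, and 0 passed when adjusted over the list alone by limma (median −0.04, camera adjusted p = 0.939). Cxcl10 lost its call when either of 2 arrays was left out. Without the 4 arrays it stood at 2.11 and missed the threshold (limma adjusted p = 0.128).

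Structural and vascular genes moved in both directions. Of 26 collagen and extracellular matrix genes 5 rose and 3 fell, also when adjusted over the list alone (median 0.14, camera with Benjamini-Hochberg adjusted p = 0.386). The basement membrane collagen gene Col4a2 rose by 0.83 ± 0.11 (SE) on the log2 scale and the thrombospondin gene Thbs1 by 1.01, and the laminin gene Lama2 fell by 0.76 ± 0.11. Of 14 endothelial markers 4 rose and 1 fell, also when adjusted over the list alone (median −0.03, adjusted p = 0.939), with Robo4 up by 0.45, Cdh5 up by 0.29 and the angiopoietin receptor gene Tek at −0.61. Cdh5 lost its call when either of 2 arrays was left out. Without the 4 arrays with high neuronal transcripts it stood at 0.37 and missed the threshold (limma adjusted p = 0.062). Of 12 pericyte and smooth muscle markers 2 rose and 3 fell, and 3 rose and 4 fell when adjusted over the list alone (median 0.02, adjusted p = 0.939). The myosin kinase gene Mylk rose by 1.09, while Smtn and Myh11, genes of contractile smooth muscle, stood at −0.77 and −1.13. Myh11 lost its call when either of 2 arrays was left out. It missed the threshold at −1.27 without the 4 arrays (limma adjusted p = 0.109) and passed at −1.76 in arrays 404 to 411 (limma adjusted p = 0.0232). Of 7 perineurial markers 0 passed by limma in either count (median −0.15, adjusted p = 0.939), and Krt19 had the smallest p of the list at a log2 change of 0.61 (limma adjusted p = 0.0993). Skeletal muscle markers spread widely within both groups, with list means from 6.56 to 11.76 in db/+ and from 6.05 to 11.28 in db/db. Of the 17, 0 passed by limma in either count (median −0.77, camera adjusted p = 0.251), and Pvalb stood at −2.06 (limma adjusted p = 0.0648). The muscle list passed as lower in db/db when db/db 112 or db/db 411, the db/db arrays with its highest means, was left out (camera at the preset correlation, adjusted p = 0.0406 and 0.0126). Of the 2 measured erythroid genes 0 passed (median 0.13, camera adjusted p = 0.975), and Slc4a1 stood at 0.19 (limma adjusted p = 0.87).

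Single genes of energy metabolism and stress responses passed the threshold, as did 3867 of all 15437 genes. The lists did not pass camera over all arrays. Of 35 oxidative phosphorylation genes 4 rose and 1 fell over all genes, and 0 passed when adjusted over the list alone by limma (median 0.05, camera with Benjamini-Hochberg adjusted p = 0.251). Cox5a and Sdhc rose by 0.24 and 0.20 on the log2 scale and Atp5g1 fell by 0.89. Without db/+ 101, 103, 104 and 106 they stood at 0.26, 0.24 and −0.61, and all 3 missed the threshold (limma, Benjamini-Hochberg adjusted p = 0.102, 0.104 and 0.133). Cox5a also lost its call when any 1 of 8 arrays was left out and Sdhc when any 1 of 7 was. Of 15 measured genes of the glycolysis and polyol pathway list 2 rose and 4 fell, also when adjusted over the list alone (median −0.12, camera adjusted p = 0.61), but the polyol pathway genes Akr1b3 and Sord were not among the probe sets paired with a symbol and were not tested as such. The phosphofructokinase gene Pfkl rose by 0.98 and Tpi1 by 0.35, and Eno2, the neuronal enolase, fell by 1.41. Eno2 stood at −0.65 without the 4 arrays and lost its call (limma adjusted p = 0.0535), while Pfkl and Tpi1 kept theirs. Of 22 antioxidant genes 4 rose and 1 fell, also when adjusted over the list alone (median 0.06, adjusted p = 0.505), with the mitochondrial superoxide dismutase gene Sod2 up by 0.73 ± 0.07 (SE), Sod3 up by 1.16 ± 0.24 and Gpx3 at −0.57 ± 0.12. Of 20 endoplasmic reticulum stress genes 3 rose and 1 fell, also when adjusted over the list alone (median −0.02, adjusted p = 0.975), with Edem1 and Atf3 both up by 0.88 and Pdia3 at −0.51. Without the 4 arrays Atf3 and Pdia3 stood at 0.83 and −0.65 and missed the threshold (limma adjusted p = 0.0656 and 0.0508). Of this list 1 member passed there as higher and 3 as lower (median −0.13). Of 18 apoptosis regulators 3 rose, and 2 when adjusted over the list alone (median 0.16, adjusted p = 0.263), and Casp8, Bak1 and Fas rose by 0.90, 0.72 and 0.50. Without the 4 arrays these rises were 0.56, 0.30 and 0.21 and missed the threshold (limma adjusted p = 0.259, 0.324 and 0.329), and Fas also missed it with the number series as a block (0.0601) and when any 1 of 8 arrays was left out. Of 17 circadian clock genes 2 rose, also when adjusted over the list alone (median 0.03, adjusted p = 0.61), with Clock up by 0.47. Of 17 immediate early genes 2 rose and 2 fell, and 2 rose and 0 fell when adjusted over the list alone (median −0.30, adjusted p = 0.431). Fosl1 rose by 1.68, Egr3 rose by 0.34 and Fosb fell by 1.38. Without the 4 arrays Fosl1 and Egr3 stood at 1.30 and 0.165 and missed the threshold (limma adjusted p = 0.0968 and 0.329). Egr3 lost its call when any 1 of 5 arrays was left out and Fosb when any 1 of 10 was. Fosb also missed the threshold after renewed quantile normalization (limma adjusted p = 0.0642). Of 20 insulin and leptin signalling genes 1 rose and 3 fell, and 1 rose and 2 fell when adjusted over the list alone (median 0.03, adjusted p = 0.939). The binding protein gene Igfbp3 rose by 1.71 ± 0.21 (SE), Igfbp5 fell by 0.36, and Lepr is given above. Igfbp5 lost its call when any 1 of 5 arrays was left out. Without the 4 arrays it stood at −0.46 and missed the threshold (limma adjusted p = 0.0908).

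For several lists that did not pass, the median, the mean of the members and camera's direction differed in sign. Medians lay below 0 and means above 0 for the cholesterol, fatty acid synthesis, lymphocyte, endoplasmic reticulum and interferon lists, and the reverse held for the pericyte list. Camera's direction was up for the cholesterol, fatty acid synthesis, lymphocyte and endothelial lists, although their medians were negative, and down for the pericyte and insulin lists, although their medians were positive.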

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

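Of the tests in this part, those of sensory ganglion and central nervous system genes, of genotype, of dilution, of ganglion RNA among the lower genes and the neuronal list, and of the difference between the number series in gene lists were chosen after the results were seen. The splits, the number series on the principal component and the genes beside Lepr were chosen beforehand.

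The neuronal list mean was between 11.77 and 12.49 in db/+ 101, 103, 104 and 106 and between 6.91 and 8.59 on the other 9 arrays. Genotype alone does not account for this division, since db/+ 105, 404 and 407 have the genotype of the 4 arrays and lay at 8.59, 8.02 and 7.62. In the test of genotype, 1 of the 7 db/+ arrays (db/+ 407) lay below the highest db/db array (7.80), by a margin inside the spread of the db/db arrays. The number series does not account for the division either, since the gap between series among db/+ arrays on the first principal component was 0.78 of the range within samples 101 to 106. Of 16 measured sensory neuron and satellite glia genes, 81.2% were higher in each of the 4 arrays than in each of the other 9, against 8.4% of all genes. Calcb lay at 12.11 to 12.80 against 4.16 to 6.76, Avil at 12.04 to 12.48 against 6.23 to 8.03 and Fabp7 at 12.48 to 12.80 against 6.93 to 10.59. This list was written after the division was seen. Its Scn11a was already among the 10 greatest falls, and 2 of its genes are also in the other lists, so the share is not an independent test. Of 14 central nervous system genes 50% were so separated, with Mog at 7.37 to 10.04 against 3.64 to 4.22 but Gja1 at 11.96 to 12.51 against 12.12 to 12.46, which leaves spinal cord or brain tissue open. Within arrays 404 to 411 the neuronal list had a median change of −0.32 against −3.34 over all arrays, so RNA of sensory ganglia is a candidate source of most of that fall, as a hypothesis, while whether ganglia were taken with the nerve or the 4 arrays hold ganglion RNA under a nerve label was not tested, and both stay open with a difference between the animals.

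Of 100 splits into 7 and 6, drawn from 1716 possible ones, 1, the real one, gave as many as 3867 changed genes, and the highest other split gave 33. Such a count is thus unlikely from a random grouping if the arrays are independent, which the labels do not state. Few of the other drawn splits kept db/+ 101, 103, 104 and 106 together. Genes called higher in arrays 101 to 112, which hold db/+ 101, 103, 104 and 106, had a median log2 change of 0.50 in arrays 404 to 411, which hold none of them, against 0.83 in the first set and −0.03 for all genes in the second, so dilution by ganglion RNA in those 4 arrays could not account for the rises as a whole. Genes called lower in arrays 101 to 112 had a median of −0.42 in arrays 404 to 411 against −1.07, which leaves open how much of the falls ganglion RNA accounts for. An effect of the db mutation on the nerve and a difference in the tissue around it, such as fat, stay open.

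Sequence linked to the db mutation on chromosome 4 might differ between the genotypes, which the labels do not state, and might change genes beside Lepr. Among the 100 measured genes nearest to Lepr, 50 on each side, 20% were called changed, against 25.2% of 14672 other genes (one-sided Fisher's exact p = 0.908). Changed genes were thus no more frequent there, so there was no excess to explain. Single genes were not tested for linked sequence, which stays open for them, such as Dnajc6, chosen after its values were seen, which lies near Lepr and stood at 0.88 over all arrays (limma, Benjamini-Hochberg adjusted p = 0.247) and at 2.35 without db/+ 101, 103, 104 and 106 (adjusted p = 0.000112).

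In 13 of 242 tests of named genes and lists within a genotype (5.4%, where chance gives about 5%), 1 array stood far from the others, by the ratio of its gap from the nearest array to the range of the group. Of these, 0 were lists. Among db/+ arrays the ratio was 0.673 for Ighg1 (low in db/+ 404, 3.35 against 4.42 for the next), 0.576 for Chil3 (high in db/+ 407, 9.89 against 6.22), 0.608 for Dgat2 (low in db/+ 101, 11.55 against 12.34), 0.672 for Pdia3 (high in db/+ 407, 11.19 against 10.76), 0.569 for Il18 (high in db/+ 407, 11.89 against 11.48) and 0.613 for Fosb (high in db/+ 105, 10.37 against 8.15). Among db/db arrays it was 0.75 for Prr32 (low in db/db 409, 10.08 against 10.77), 0.735 for Thbs1 (high in db/db 409, 11.01 against 10.65), 0.65 for Clock (low in db/db 409, 11.03 against 11.29) and 0.81 for Cxcl10 (high in db/db 409, 12.67 against 9.34). It was 0.65 for Cyp2f2 (low in db/db 110, 5.09 against 6.63), 0.634 for Btc (low in db/db 110, 8.20 against 9.12) and 0.663 for Pvalb (high in db/db 411, 13.12 against 9.93).

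The genotype change of 11 gene lists differed between arrays 404 to 411 and arrays 101 to 112 by camera on the interaction term, with Benjamini-Hochberg adjustment over 29 lists. The median difference, the change in 404 to 411 minus that in 101 to 112, was 4.10 for neuronal transcripts (adjusted p = 1.38e-11), 1.03 for ion channels (adjusted p = 0.000677), 0.61 for repair Schwann cells (adjusted p = 0.0324), 0.54 for cholesterol synthesis (adjusted p = 2.26e-05) and 0.47 for glycolysis (adjusted p = 0.0345). It was −1.66 for the cell cycle (adjusted p = 2.34e-08), −0.50 for macrophages (adjusted p = 0.00033), −0.42 for endoplasmic reticulum stress (adjusted p = 0.000205), −0.42 for extracellular matrix (adjusted p = 0.000917), −0.40 for pericytes (adjusted p = 0.0201) and −0.35 for adipocytes (adjusted p = 0.0153). With an estimated correlation 0 of the 29 lists passed in camera (adjusted p = 0.461 to 0.795), and limma's interaction called 0 genes, with 2360 at an unadjusted p below 0.05. All 4 arrays with high neuronal transcripts are in the lower series.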

How the results depend on the processing

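Leaving out db/+ 101, 103, 104 and 106, with or without the series as a block, the neuronal list mean as a covariate and an estimated correlation within sets of arrays were tests chosen after the results were seen, and the other alternatives were planned. Lepr was lower in db/db and passed the threshold in every alternative that tested it (log2 change −1.07 to −2.81, the last with the adipocyte covariate, limma with Benjamini-Hochberg adjusted p = 9.81e-05 to 0.0287); the filter above the median level removed it. The count of 3867 changed genes (2068 higher, 1799 lower) stayed within 1.5 times with an intensity trend, robust moderation, renewed quantile normalization, median centring, the milder dim filter, the number series as a block, arrays 101 to 112 alone and the exact rank-sum test (3119). Leaving out each array gave 2893 to 4529 genes, 1621 to 2376 higher and 1267 to 2153 lower. With array weights the count was 6525 (3581 higher, 2944 lower). The weights were 0.549, 0.422 and 0.331 for db/+ 105, 404 and 407 and 0.807 to 1.77 for db/+ 101, 103, 104 and 106. Among db/+ arrays the weighted fit thus leaned on the 4 with high neuronal transcripts, so its larger count is not separate support. The count was 2403 (990 lower) above the median level, where fewer genes were tested, and 1404 (761 higher, 643 lower) in arrays 404 to 411, which are fewer. It was 1992 (945 and 1047) without db/+ 101, 103, 104 and 106 and 2073 (953 and 1120) with the neuronal covariate, 541 (236 and 305) with the adipocyte covariate, where 146 of the higher genes turned negative and 224 of the lower genes positive, and 2987 without the 4 arrays and with the series as a block. A size of at least 1 on the log2 scale left 1217 genes (561 and 656), and a size of at least 0.5 left 1357 higher genes. Median centring called 62.6% of changed genes higher against 53.5%, with a median shift of all genes of 0.066. Of 29 lists, 7 passed camera, and 6 to 9 when each array was left out. With the adipocyte list mean as a covariate 2 passed, and the adipocyte list could hardly pass, since the covariate is its own mean. With an estimated correlation 0 passed, over all arrays, in either number series, with the series as a block and without the 4 arrays. By fry, which tests each list without comparing it with other genes, 8 passed over all arrays. These were the same 7 (fry adjusted p = 0.00103 to 0.0405) and the antioxidant list (fry adjusted p = 0.0376). The filters on dim genes ended the calls of the repair Schwann cell list (adjusted p = 0.0619 and 0.118) and the ion channel list (adjusted p = 0.0619 and 0.561). Leaving out 1 array added the macrophage list (without db/+ 105, db/+ 407 or db/db 410, adjusted p = 0.0408, 0.00562 and 0.0153), the cytokine list (without db/+ 105, db/+ 407, db/db 112 or db/db 410, adjusted p = 0.0231 to 0.0321) and the mast cell list (without db/+ 106 or db/db 409, adjusted p = 0.0382 and 0.0477). Array weights added the macrophage and cytokine lists (camera adjusted p = 0.01 and 0.0236), and the lymphocyte covariate added the mast cell list (camera adjusted p = 0.0357). The oxidative phosphorylation list passed without the 4 arrays and with the series as a block (median 0.07, camera adjusted p = 0.036). The neuronal covariate is the neuronal list's own mean, so the average genotype change of its members is 0 by construction. The lost call of that list there (median −0.21) was therefore largely fixed in advance. Its turned direction was not, since camera compares the members with all other genes, and the median of all genes there was −0.047. Camera's direction also turned for the neuronal list with the adipocyte covariate (−0.032) and for the ion channel list with the neuronal and adipocyte covariates (−0.035 and −0.015). Neither list passed there, the covariates differ between genotypes, and the cause of these turns was not tested. Nap1l2 turned to 0.13 in arrays 404 to 411, and Scn11a and Slc17a6 to 0.18 and 0.23 with the neuronal covariate, none past the threshold. Of 91 genes named besides Lepr, 37 lost their call without the 4 arrays, 51 in arrays 404 to 411 besides Nap1l2, 16 in arrays 101 to 112, and 0 to 8 when each array was left out. A change of sign counts as a turn only where a call had been made over all arrays. Camera has no robust moderation, so lists were not run with it, and counting probe sets gave the same genes. No paired analysis was possible because the groups share no sample numbers. Levels near background were not marked in the deposited values, so folds of dim genes such as Lipf in db/+ are less certain than those of bright genes.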

Other observations

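All tests in this part, of single genes and of control probe sets, were chosen after the results over all arrays were seen. Among genes outside the rule for named genes, chosen after their values were seen, several were lower in db/db without db/+ 101, 103, 104 and 106 and also in arrays 404 to 411, which are 5 of the 9 arrays left. Without the 4 arrays, Pon1, which encodes the lipoprotein-bound enzyme paraoxonase, fell by 4.34 ± 0.35 (SE) on the log2 scale (limma, Benjamini-Hochberg adjusted p = 0.000208), and the estrogen sulfotransferase gene Sult1e1 fell by 4.02 ± 0.22 (adjusted p = 1.85e-05). Stmn4 fell by 2.63, the claudin gene Cldn10 fell by 2.57, the phosphatidylserine receptor gene Timd4 fell by 2.52, the thiosulfate sulfurtransferase gene Tst fell by 2.39, Igsf1 fell by 2.36 and the monoacylglycerol acyltransferase gene Mogat1 fell by 2.30.

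Other genes of this kind were higher in db/db. Without the 4 arrays the macrophage elastase gene Mmp12 rose by 4.69 ± 1.18 (SE) on the log2 scale (limma, Benjamini-Hochberg adjusted p = 0.0313), S100a7l2 by 4.53 ± 0.59, Ct55 by 4.31 ± 0.22, the GABA receptor gene Gabrr2 by 4.26 ± 0.42 and Plppr4 by 4.09 ± 0.35. The choline transporter gene Slc5a7 rose by 3.77 ± 0.17, 9030619P08Rik by 3.78 and Ptchd4 by 3.73. S100a7l2 did not pass over all 13 arrays (log2 change 2.20, limma with Benjamini-Hochberg adjusted p = 0.109), and the others did.

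On the control probe sets, the 3' minus 5' difference for Gapdh, a measure of RNA integrity and of amplification, was 0.86 ± 0.25 (SD, n = 7) in db/+ and 0.73 ± 0.13 (SD, n = 6) in db/db (two-sided exact permutation p = 0.298, Benjamini-Hochberg adjusted over both controls 0.298). For actin it was 1.02 ± 0.31 and 0.68 ± 0.18 (two-sided exact permutation p = 0.0455, adjusted 0.091). The Gapdh difference was 0.72 to 0.99 in db/+ 101, 103, 104 and 106 and 0.55 to 1.34 in db/+ 105, 404 and 407. The actin difference was 0.96 to 1.39 in the first of these sets, above each db/db array (0.48 to 0.92), and 0.40 to 1.14 in the other. Of 18 spike-in probe sets, 9 (50%) were higher and 0 were lower on each of arrays 404 to 411 than on each of arrays 101 to 112. Chance separates 0.155% in either direction, and 5.99% of genes were so separated. A cre spike-in lay between 15.50 and 16.37 in arrays 404 to 411 and between 14.80 and 15.07 in arrays 101 to 112.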
